A study of Caenorhabditis elegans with 2 samples.

How the data were processed

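The data came from chromatin immunoprecipitation with sequencing (ChIP-seq), in which DNA crosslinked to a protein is recovered with an antibody and sequenced. The samples were early embryos of the nematode Caenorhabditis elegans, 1 hour after synchronization by bleaching. The strain carried an integrated transgene that expresses the protein F13C5.2 with a green fluorescent protein (GFP) tag, in an unc-119 mutant background, and the antibody was directed against GFP, per the labels. The series holds 1 group with 2 biological replicates, numbered 2 and 3 in the labels. It has no second condition, so the comparisons are between replicates and between parts of the genome.

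Each replicate has a peak list on the genome builds ce10 and ce11, and each build also has a list called on both replicates together. Those lists were deposited as peaks and background intended as input for the irreproducible discovery rate (IDR) procedure, which compares the ranks of peaks between replicates. Each was called against 2 control alignments, per the deposited file descriptions. The optimal IDR-thresholded list of each build, derived by the authors from the replicate and pooled lists, held 1850 peaks on ce11 and 1894 on ce10. All 1850 ce11 peaks of the IDR list were found in the pooled list and were its 1850 highest signal values. A single IDR peak therefore need not rank alike in both replicates. The peak caller, its version, the aligner and the IDR threshold are not given in the sources used here.

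The deposited signal value of each peak is a score that the authors' caller assigned, on a scale that is not given in the sources used here. It was used only to rank and describe peaks within 1 list. The deposited lists also give a −log10 q-value per peak. On ce11 it was tied at its maximum of 3.53 for 1692 of the pooled peaks, so peaks were ranked by the signal score. The lists hold 30000 peaks per replicate and 30000 for the pooled reads, and the read depth is unknown from them. Intervals on shares of peaks or genes are 95% Wilson binomial intervals and cover counting error only. Peak lists of the controls alone were not analysed here.

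The ce11 lists were compared with the Ensembl release 115 annotation and the RefSeq genome sequence of the same assembly, on chromosomes I to V and X. The ce10 lists entered only counts and overlaps between lists of that build. A promoter window ran from 1000 bp upstream to 200 bp downstream of any annotated 5′ end of a protein-coding transcript, and a gene was called occupied when an IDR summit lay in one of its windows. A summit can therefore occupy several neighbouring genes. Summits were assigned to classes in the order promoter, 5′ UTR, coding exon, 3′ UTR, intron, non-coding gene and intergenic. The null for positions was 1000 circular shifts of the summits along each chromosome, with a two-sided permutation p of which the smallest possible value is 0.002. Summits within 500 bp of non-coding RNA genes were counted against the same shifts.

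Occupancy of gene lists, of X against autosomes and of chromosome centres (the middle 50% by length) against arms was compared with two-sided Fisher's exact tests over 19973 protein-coding genes, with Benjamini-Hochberg adjustment over the 21 gene lists and a threshold of 0.05. Canonical 6-mers were counted once per 201 bp window centred on a summit. The background was equally wide windows upstream of unoccupied genes, placed at drawn summit-to-5′-end distances. Replicate lists were compared as the share of top-ranked peaks with an overlap of 1 bp or more, against circular shifts, and by the Spearman correlation of signal between peaks with summits within 100 bp. Peaks within 20 kb of F13C5.2 and unc-119 were counted against 1000 random 40 kb windows of the same chromosome. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

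Before the data were examined, the gene lists, the tests, the alternatives and the rule for named genes were written down. The rule took F13C5.2 and unc-119, the 15 genes with the highest signal in a promoter (nearest 5′ end, 1 per peak), up to 4 members of each list occupied more often and 2 of each occupied less often than other genes, the 5 highest and 5 lowest 6-mers by odds ratio, and the gene with the most summits in its promoter. RNA genes and neighbouring genes at the summits are named outside the rule, as are the members of highest signal of families added later. The alternatives were a stricter list, other promoter windows, the outermost 5′ end, any overlap in place of the summit, each replicate alone, removal of the transgene loci, other gene or sequence backgrounds, another width of the centres, nearest 5′ ends only, other distances, depths and overlap rules, and the ce10 lists. Alternatives chosen after seeing the data left out summits near small RNA genes or chromosome V, and matched the 6-mer background on GC content.

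The tests were checked on simulated data. In 20 rounds of 21 random lists, summits planted in 50% of a list's promoters gave a call in 120 of 120 planted lists, and 4 of 300 unplanted lists were called. Lower shares, depleted lists and lists of neighbouring genes were not simulated, so the check does not cover such calls. Of 40 sets of random summits, 2 had a promoter share under the 0.05 threshold. A planted 6-mer ranked first, and 0 of the 6-mers were called without planting. The other 2 checks counted more than was planted. Summits planted at 200 tRNA genes gave 249 occupied tRNA genes, and lists that shared 925 peaks gave 987 overlapping peaks.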

Results

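F13C5.2, annotated as a bromodomain-containing protein, was profiled by ChIP-seq through its GFP tag in early C. elegans embryos of 1 strain, in 2 biological replicates. Bromodomains are modules that bind acetylated lysines, as found on histones. The lists analysed here gave 1850 IDR peaks on ce11, with signal values from 77.9 to 611, and 30000 ranked peaks for each replicate. The read depth behind them is unknown. The comparisons ask where in the genome the tagged protein was recovered, near which genes, and how well the replicates match.

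The replicates shared many of their strongest sites. The highest-ranked regions in both lists lay at a small nucleolar RNA (snoRNA) gene, W03C9.9 on chromosome II (IDR rank 1, rank 2 in replicate 2 and rank 1 in replicate 3), upstream of K12H4.5 (ranks 1 and 2) and upstream of the ribosomal protein gene rpl-3 (ranks 4 and 3). Of the top 1850 peaks of replicate 2, 1146 overlapped a top 1850 peak of replicate 3, which is 61.9% (95% Wilson interval 59.7 to 64.1%). Circular shifts gave a mean of 1.59% and at most 2.81% (two-sided permutation p = 0.002, the smallest possible). In the other direction 1172 peaks, or 63.4%, overlapped. Among the top 500 peaks of each list the overlap was 61.2%, no higher than among the top 1850. Agreement with the whole replicate 3 list, whatever the rank there, fell with the rank in replicate 2. No shifts were run for these shares. A replicate 3 summit lay within 100 bp of 97.2% of the replicate 2 peaks ranked 1 to 500, of 76.6% of those ranked 1001 to 1850, and of 12.6% of those ranked 20001 to 30000. Across the 7416 peaks matched between the full lists, Spearman's rho of signal was 0.59, a value across peaks, which are not independent replicates. Of the 1850 IDR peaks, 1695 (91.6%) had a matching summit in both replicate lists and 1021 (55.2%) ranked in the top 1850 of both, and rho between the replicates among the matched IDR peaks was 0.39. The IDR list was derived from these same replicates, so a high share of matches is partly built in, and this rho describes a selected set.

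**Figure D1:**
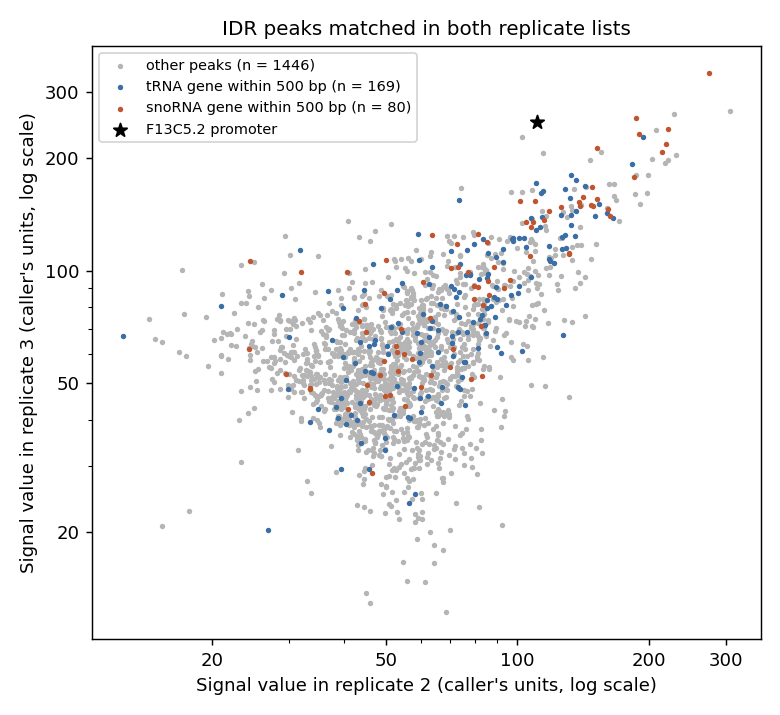
Signal value in replicate 2 (horizontal, log scale) and replicate 3 (vertical, log scale) for the 1695 IDR peaks matched in both lists, in the caller's units. Blue points have a tRNA gene and red points a snoRNA gene within 500 bp of the summit, the star is the F13C5.2 promoter, and the strongest peaks fall along a diagonal while weaker peaks scatter.

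The IDR summits lay mainly just upstream of genes. Of the 1850 IDR summits, 1255 (67.8%) lay in a promoter window of a protein-coding gene, against a mean of 25.5% in circular shifts (SD 1.02 over 1000 shifts), an excess of 2.66-fold. Coding exons held 5 summits (0.27% against 18.8% in shifts), introns 229 (12.4% against 27.9%), 3′ UTRs 2 (0.108% against 2.39%) and intergenic sequence 274 (14.8% against 24.1%). Bodies of non-coding genes outside promoters held 81 summits (4.38% against 0.794%), 5.52 times the shifts. Each of these classes differed from the shifts (two-sided permutation p = 0.002, adjusted p = 0.0023), and the 4 summits in 5′ UTRs did not (0.216% against 0.428%, adjusted p = 0.22). Promoter summits lay at a median of -193 bp from the nearest 5′ end (interquartile range -339.5 to -106.5 bp), and 93.5% were upstream of it. Shifted summits inside promoter windows gave a mean of 80.7% upstream, since the windows reach further upstream than downstream, and a mean median of -343 bp (two-sided permutation p = 0.002 for both, the smallest possible, in a comparison chosen after the observed values were seen). In all, 1700 of 19973 protein-coding genes (8.51%) had a summit in a promoter window.

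The strongest promoter peaks lay at genes of varied function. K12H4.5, which encodes an uncharacterized protein, had the highest promoter signal (576, IDR rank 2, chromosome III 8043799 to 8044159, summit at -516 bp). It was followed by rpl-3 (492, rank 3, summit at -272 bp) and the 14-3-3 gene ftt-2 (445, rank 5). Next came egg-5, an inactive tyrosine phosphatase of the egg-to-embryo transition (427, rank 8), and the chemoreceptor gene sre-23 (423, rank 9). The summits at egg-5, sre-23 and T02E1.2 (415, rank 13) each had a small RNA gene within 500 bp, sls-2.4 (annotated as a small nuclear RNA), the snoRNA gene ZK265.10 and the snoRNA gene T02E1.9. Others among the first 15 were the taspase homolog tasp-1 (421), the ribosomal protein gene rpl-15 (416), the AAA ATPase gene cdc-48.1 (376), the mitochondrial glutamyl-tRNA synthetase gene ears-2 (371) and atx-2, the ataxin-2 homolog (361). Y17G9B.5 (359) shares its peak with the divergent gene rpl-20. F13C5.2 itself (355), T13C5.6 (334) and nspc-17 (328) complete the 15. The gene with the most IDR summits in its promoter windows was nurf-1, a subunit of the NURF chromatin remodeler, with 3. Windows were placed at every annotated 5′ end, so genes with several can collect more summits. The strongest nurf-1 summit, at 14405304, lay inside the gene (14390713 to 14407911), at -128 bp from an internal 5′ end.

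Genes for protein synthesis, energy metabolism and chromatin were occupied far more often than other genes. The lists were not matched on expression, and no list from an untagged strain was analysed here. Non-specific recovery at highly transcribed genes was therefore not separated from binding by F13C5.2, here or for the lists occupied less often. Of 78 ribosomal protein genes, 58 (74.4%) had a promoter summit, against 8.25% of other genes (odds ratio 32.2, two-sided Fisher's exact test, adjusted p = 2.7e-44), with rpl-3, rpl-15, rpl-20 and rpl-35 (signal 319) the strongest. Respiratory chain and ATP synthase genes followed with 23 of 43 (53.5%, odds ratio 12.5, exact-test adjusted p = 2.7e-13), led by cox-5B (217), cox-5A (198), nuo-2 (190) and cox-6B (178). Translation factors had 21 of 40 (52.5%, odds ratio 12, exact-test adjusted p = 3.6e-12), among them eif-3.C (266), iff-2 (251), eef-1A.1 (188) and eef-2 (179). Chromatin regulators had 22 of 44 (50%, odds ratio 10.9, exact-test adjusted p = 3.6e-12). F13C5.2 is a member of that list, and next were the CBP/p300 acetyltransferase gene cbp-1 (257, rank 75), the chromodomain gene mrg-1 (208) and lin-35, the retinoblastoma homolog (197). Spliceosome genes had 18 of 48 (37.5%, odds ratio 6.51, exact-test adjusted p = 1.1e-07), with lsm-3 (185), snr-1 (166), rsp-6 (166) and rnp-6 (150). Proteasome subunits had 12 of 33 (36.4%, odds ratio 6.18, exact-test adjusted p = 2.4e-05), with rpn-7 (204), rpn-3 (165), rpn-13 (132) and rpt-4 (111). Several of these summits lie between divergent or neighbouring genes. Another gene has the nearest 5′ end at rpl-20, cox-6B, eef-1A.1, mrg-1, lin-35, lsm-3, snr-1, rnp-6, rpn-7 and rpt-4. With each summit given only to the nearest 5′ end, the occupied shares fell to 46.2% of ribosomal protein, 31.8% of chromatin regulator and 18.8% of spliceosome genes, still past the threshold. With the 50% of IDR peaks of higher signal, the proteasome call was lost (12.1% of genes, exact-test adjusted p = 0.12). The other calls named here remained at lower shares: 53.8% of ribosomal protein, 40% of translation factor, 29.5% of chromatin regulator, 25.6% of respiratory chain and 16.7% of spliceosome genes.

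Smaller excesses were seen for cell cycle and heat shock genes and for histones. Cell cycle and DNA replication genes had 10 of 41 occupied (24.4%, odds ratio 3.48, exact-test adjusted p = 0.0036), led by wee-1.3 (139), cdc-6 (123), pcn-1 (107) and cdk-4 (102). The summit at cdc-6 is nearest to acin-1. Heat shock protein genes had 5 of 22 (22.7%, odds ratio 3.17, exact-test adjusted p = 0.048), including the Hsp70 gene hsp-1 (273, rank 63), hsp-60 (218), hsp-110 (165) and hsp-3 (139); the summit at hsp-60 is nearest to Y22D7AL.10, and that at hsp-110 is the peak of rpn-3. Histone genes had 13 of 80 (16.3%, odds ratio 2.09, exact-test adjusted p = 0.036), with his-67 and his-68 sharing a peak of signal 203, his-24 at 114 and his-61 at 110. The 13 histone genes rested on 9 distinct strongest summits, because paired histone genes share promoters. The histone call and the heat shock call were each lost under 5 alternatives, with a heat shock share from 9.09% with nearest 5′ ends to 36.4% without replicate 2, and the cell cycle call was lost with the 50% of IDR peaks of higher signal (4.88% of genes, exact-test adjusted p = 0.76).

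**Figure D2:**
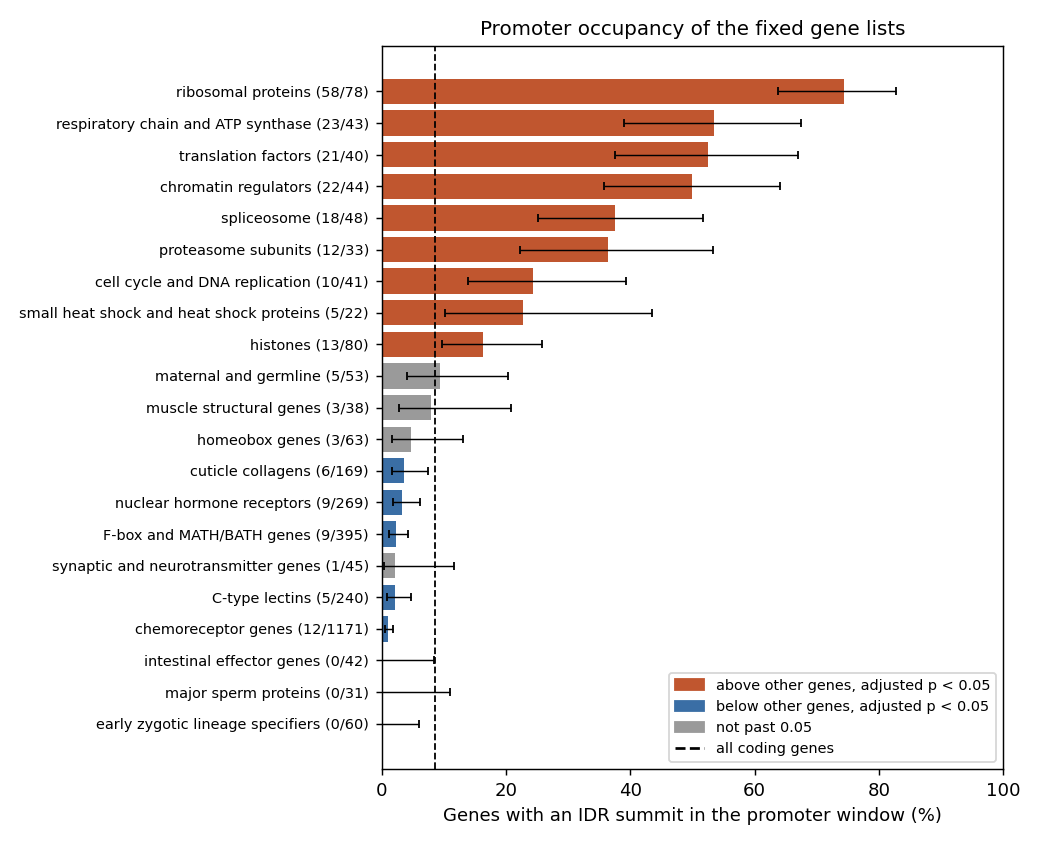
Share of the genes of each fixed list with an IDR summit in the promoter window (horizontal axis, percent), with 95% Wilson intervals as error bars and occupied over total genes in parentheses. The dashed line marks all protein-coding genes (8.51%); orange lists lay above and blue lists below other genes, and the early zygotic lineage specifiers (0 of 60) were also below.

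Genes of the chemoreceptor, F-box and MATH/BATH, C-type lectin, nuclear hormone receptor, collagen and early zygotic lists were occupied less often than other genes. Among 1171 chemoreceptor genes, 12 (1.02%) had a promoter summit (odds ratio 0.105, exact-test adjusted p = 4.4e-30), with sre-23 and sri-5 (254) the strongest. F-box and MATH/BATH genes had 9 of 395 (2.28%, odds ratio 0.247, exact-test adjusted p = 1.1e-06), with fbxb-85 (222) and math-33 (202). C-type lectin genes had 5 of 240 (2.08%, odds ratio 0.226, exact-test adjusted p = 0.00013), with clec-53 (211) and clec-126 (154). Nuclear hormone receptor genes had 9 of 269 (3.35%, odds ratio 0.369, exact-test adjusted p = 0.0027), with nhr-255 (220) and nhr-48 (158). Cuticle collagens had 6 of 169 (3.55%, odds ratio 0.394, exact-test adjusted p = 0.028), with col-185 (182) and col-38 (137). A tRNA gene lies within 500 bp of the summits at nhr-255, col-185 and clec-126, and other genes have the nearest 5′ end at math-33, clec-53 and col-38. Without replicate 2 the calls of nuclear hormone receptors (4.83%, exact-test adjusted p = 0.16) and cuticle collagens (3.55%, adjusted p = 0.082) were lost, and the share of C-type lectins was 1.25%. The early zygotic call was lost with the 50% of IDR peaks of higher signal (exact-test adjusted p = 0.19) and with nearest 5′ ends (adjusted p = 0.084). None of the 60 early zygotic lineage specifiers had a promoter summit (0%, exact-test adjusted p = 0.016). That list is broad, with members such as lin-39, egl-5, unc-30 and tps-1. Its share therefore does not stand for early zygotic genes as a class.

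Other tissue and stage lists did not pass the threshold by the same Fisher's exact test. Maternal and germline genes had 5 of 53 occupied (9.43%, exact-test adjusted p = 0.84), muscle structural genes 3 of 38 (7.89%, adjusted p = 1), homeobox genes 3 of 63 (4.76%, adjusted p = 0.41) and synaptic genes 1 of 45 (2.22%, adjusted p = 0.21). With single replicates the share was 10.5 to 13.2% for muscle genes, a change of direction, and 4.44% in both for synaptic genes, and maternal genes changed direction under 4 alternatives, down to 1.89% with nearest 5′ ends. Intestinal effector genes had 0 of 42 (exact-test adjusted p = 0.062) and major sperm protein genes 0 of 31 (adjusted p = 0.13). In total 9 of 21 lists were occupied more often than other genes, 6 less often, and 6 did not pass. Among the 6 less occupied lists, 3 were still called with the 50% of IDR peaks of higher signal.

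Small RNA genes were a further location of peaks. Of the IDR summits, 191 (10.3%) lay outside promoters within 500 bp of a tRNA, snoRNA or small nuclear RNA gene, and a larger group of 404 (21.8%) lay outside promoters and near none of them. Of 612 tRNA genes, 194 (31.7%) had an IDR summit within 500 bp, 15.1 times the mean of the circular shifts (12.8 genes). Of 346 snoRNA genes, 88 (25.4%) did, 12.2 times the shifts, and of 129 small nuclear RNA genes, 18 (14%, 7.78 times). MicroRNA genes had 21 of 261 (8.05%, 3.79 times), and long intergenic and other non-coding RNA genes had 586 of 7958 (7.36%, 3.36 times). The piRNA genes, germline small RNA genes, were less often near a summit than in the shifts, with 72 of 15363 (0.469%, 0.302 times). All of these classes had adjusted p = 0.0023 in the two-sided permutation test. The shifts do not keep the 2.66-fold excess of summits in coding promoters. Only tRNA genes were also examined away from coding 5′ ends. Whether the excess at the other classes goes beyond nearness to coding promoters was not tested. Of 20 rRNA genes, 0 had a summit (permutation adjusted p = 1). The miRNA call was lost at a distance of 200 bp, where 7 genes had a summit (permutation adjusted p = 0.068).

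Peaks at small RNA genes were also strong. The 86 summits near snoRNA genes included 16 of the 50 strongest IDR peaks, and the 180 summits near tRNA genes included 9. Median signal was 165 for peaks near snoRNA genes and 146 for peaks near tRNA genes, against 106 and 105 for the IDR peaks not near such a gene. Beside W03C9.9 (signal 611), the snoRNA genes C51F7.4, Y43F8C.22 and T06C12.16 and the tRNA-Leu gene C04A11.t1 had peaks among the first 10 of the IDR list. These genes were chosen after their values were seen. Of the 180 summits near tRNA genes, 176 lay within 100 bp of the gene and 134 were outside every promoter window, against 48 of the 86 near snoRNA genes and 10 of the 21 near small nuclear RNA genes.

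**Figure D3:**
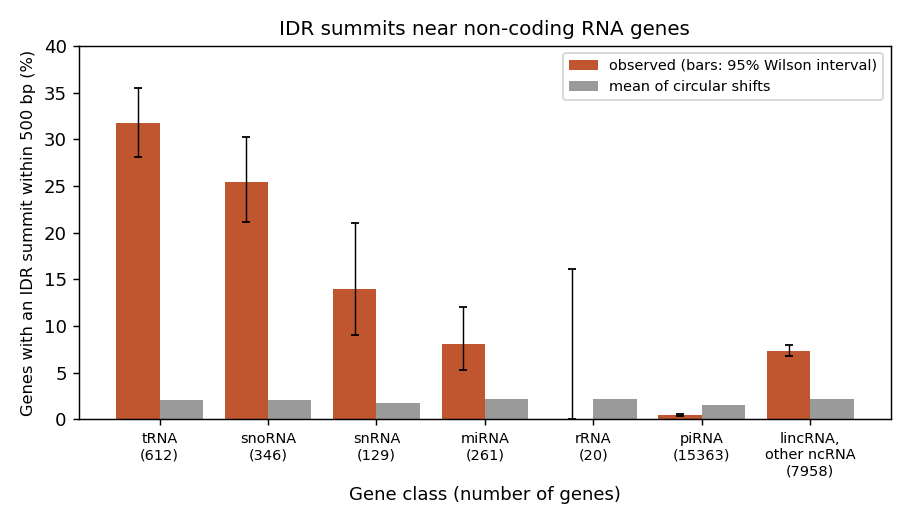
Share of the genes of each non-coding class with an IDR summit within 500 bp (vertical axis, percent), observed in orange with 95% Wilson intervals and as the mean of 1000 circular shifts in grey. tRNA (31.7%) and snoRNA genes (25.4%) stand highest, and piRNA genes (0.469%) lie below their shifts.

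IDR peaks were unevenly spread over chromosomes. The X chromosome held 410 peaks, 22.2% of the list (95% Wilson interval 20.3 to 24.1%) for 17.7% of the length, or 23.1 per Mb against 17.4 per Mb on the autosomes together. Chromosomes III (23.4 per Mb) and I (22.5 per Mb) were as dense as X, and V was the sparsest (11.1 per Mb). X carries 276 of the 612 tRNA genes (45.1%). Without summits within 500 bp of a tRNA gene, X had 18.5 peaks per Mb and the autosomes 16.3.

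Promoter occupancy of X genes lay within the range of the single autosomes. Of 2731 protein-coding genes on X, 243 (8.90%) were occupied, against 1457 of 17242 (8.45%) on autosomes (odds ratio 1.06, two-sided Fisher's exact test, p = 0.44). Without replicate 2 the odds ratio was 1.21 (exact test, p = 0.010), and without replicate 3 it was 0.888 (p = 0.12), so the comparison differs between the replicate lists. Against single autosomes, by unadjusted exact tests, X was lower than I (odds ratio 0.736, p = 0.00061) and III (0.677, p = 1.2e-05) and higher than V (1.94, p = 2.8e-12), so the pooled value averages opposite differences.

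Genes in chromosome centres were occupied slightly more often than genes on the arms, 1005 of 11042 (9.10%) against 695 of 8931 (7.78%), with an odds ratio of 1.19 (two-sided Fisher's exact test, p = 0.00091). On chromosome V the shares were 6.52% and 2.87% (odds ratio 2.36, exact test, p = 1.0e-09), and on chromosome II 9.60% and 6.82% (odds ratio 1.45, p = 0.0036). The exact-test p-values for single chromosomes are not adjusted, and those of I, III, IV and X were above 0.05. The odds ratio was 1.07 on I, while III (0.986), IV (0.899) and X went the other way. On X the shares were 8.02% in the centre and 9.88% on the arms (exact test, p = 0.093). The overall call was lost without chromosome V (odds ratio 1.04, exact test, p = 0.49), an alternative chosen after seeing the data, and without receptor, F-box, MATH/BATH and lectin genes (odds ratio 1.06, p = 0.25). It was also lost with the 50% of peaks of higher signal (1.02) and without replicate 2 (1.05).

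**Figure D4:**
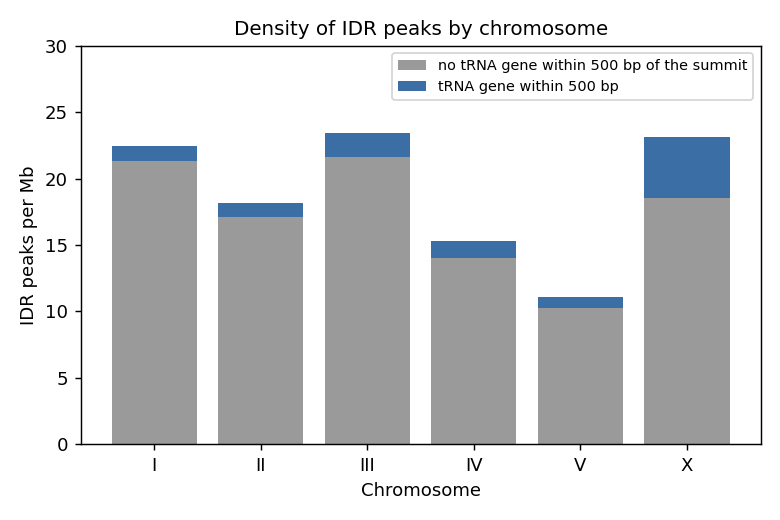
IDR peaks per Mb (vertical axis) on each chromosome, split into peaks with a tRNA gene within 500 bp of the summit (blue) and the others (grey). The tRNA-associated part is largest on X, where the total is 23.1 per Mb and the rest 18.5 per Mb.

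Summit sequences were rich in G and C. The 201 bp windows had 44.8% GC against 34.5% in windows upstream of unoccupied genes. Of 2080 canonical 6-mers, 882 were more frequent and 678 less frequent at summits (two-sided Fisher's exact test, Benjamini-Hochberg adjustment). The highest odds ratios were those of GCGCGC (14.5% of windows against 1.65%, odds ratio 10.1), GCGCAC (20.6% against 2.97%, odds ratio 8.50), CGCGCG (8), ACGCGC (7.95) and CGCGCA (7.62). The lowest were those of CTGTAA (2.16% against 9.82%, odds ratio 0.203), AGATCA (0.243), TACCTA (0.263), GGATCA (0.263) and CTATAA (0.269). With single replicates these odds ratios were less extreme, from 0.266 (CTGTAA, without replicate 2) to 0.389 (CTATAA, without replicate 3). Against 798 unoccupied promoter windows drawn to the same GC content, chosen after seeing the data, 266 6-mers were more and 392 less frequent. There GCGCGC had an odds ratio of 3.69, GCGCAC of 3.81 and CGCGCG of 2.74. The main background held 18250 windows, so the matched test has less power and the fall in calls does not measure GC content alone.

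The promoter of the tagged gene itself carried a strong peak. At F13C5.2 (chromosome X, 593960 to 596293, plus strand), the peak from 593215 to 593789 had a signal of 355 and IDR rank 22, with its summit at -366 bp. The matching peak ranked 5 in replicate 3 and 123 in replicate 2. Within 20 kb there were 3 IDR peaks, against a mean of 0.929 in random 40 kb windows of X (permutation p = 0.19), and 26 peaks of the pooled list against a mean of 12.7 (permutation p = 0.072). The other 2 IDR peaks, which overlap each other, lay upstream of the neighbouring gene F13C5.1, with signals of 233 (no match in replicate 2) and 169. Within 10 kb the 3 IDR peaks exceeded the random windows (permutation p = 0.032), and within 50 kb the 4 IDR peaks did not (permutation p = 0.44). At unc-119 (chromosome III, 10902641 to 10908935), the gene mutated in the strain, there was no IDR peak within 20 kb, and the 14 pooled peaks were near the window mean of 15.6 (permutation p = 0.94).

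**Figure D5:**
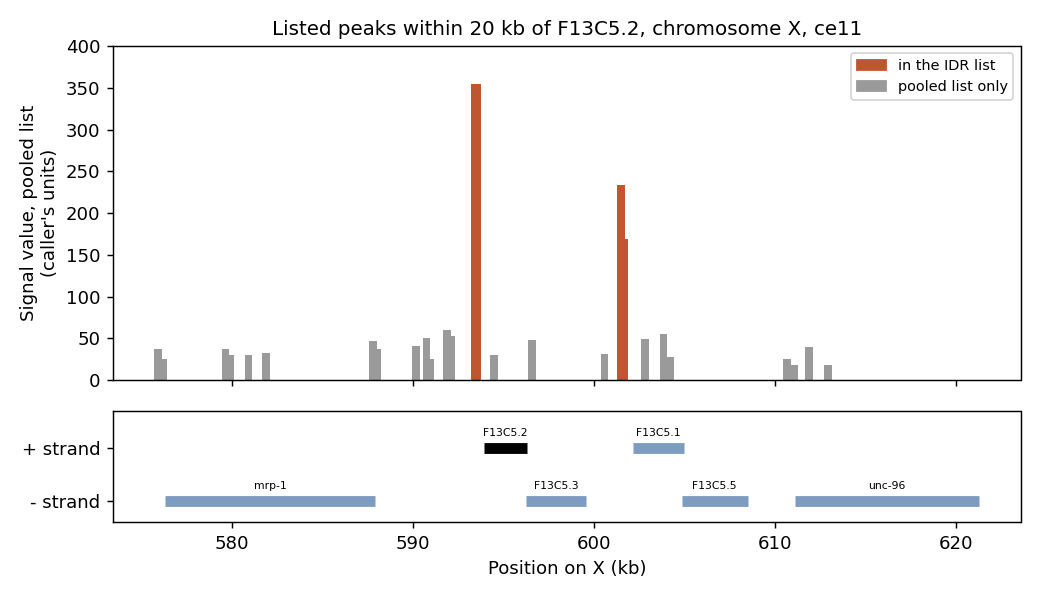
Peaks of the pooled list within 20 kb of F13C5.2 on chromosome X (horizontal axis, position in kb on ce11), with their signal in the caller's units (vertical axis). Orange bars are the 3 IDR peaks and grey bars the other listed peaks, and the lower panel shows annotated protein-coding genes by strand.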

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

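Of the comparisons recomputed under the alternatives, 299 values kept their direction and their side of the threshold or stayed close in size, and 10 changed direction, all in results that passed the threshold neither before nor after. The alternatives without summits near small RNA genes, without chromosome V and with a GC-matched background were chosen after seeing the data, and except where a construction shows it the cause of a change was not tested. With the 50% of IDR peaks of higher signal, which leaves fewer occupied genes, calls were lost for proteasome subunits (12.1% occupied), histones (6.25%), cell cycle genes (4.88%), early zygotic lineage specifiers (0%), nuclear hormone receptors (2.23%), cuticle collagens (2.96%) and centres against arms (odds ratio 1.02). There 3 lists remained below other genes in place of 6, and X held 24.3% of peaks. Histones were also lost without summits near tRNA, snoRNA or snRNA genes (13.8%), without likely downstream operon genes (15.4%) and with each summit given to the nearest 5′ end (11.3%). Heat shock genes were lost with the shorter (18.2%) and the longer promoter window (22.7%), any overlap of the peak (22.7%), no downstream operon genes (23.8%) and nearest 5′ ends (9.09%). Nearest 5′ ends also ended the call for early zygotic lineage specifiers (0%), and leaving out operon genes that for cuticle collagens (4.17%). Any overlap of the peak brought intestinal effector genes past the threshold (0%). The list calls lost with single replicates were those of histones (13.8 to 16.3% over the replicates), nuclear hormone receptors (3.35 to 4.83%) and cuticle collagens (3.55% in both). The changes of direction were those of maternal and germline genes with the shorter (3.77%) and longer window (9.43%), without operon genes (9.09%) and with nearest 5′ ends (1.89%), and of muscle structural genes with any overlap (10.5%), nearest 5′ ends (7.89%) and single replicates (10.5 to 13.2%). X against autosomes changed direction without receptor, F-box, MATH/BATH and lectin genes (0.973) and without replicate 3. With single replicates the odds ratio of X against autosomes ran from 0.888 to 1.21, past the threshold without replicate 2, and that of centres against arms from 1.05 to 1.21, lost without replicate 2. The latter was also lost without receptor, F-box, MATH/BATH and lectin genes (1.06) and without chromosome V (1.04). Without summits near tRNA genes X held 19.6% of peaks. The miRNA call was lost within 200 bp (7 genes), and the 3 IDR peaks near F13C5.2 passed the threshold within 10 kb. Spearman's rho between replicates was 0.55 over peaks that overlap the IDR list and 0.45 for overlaps of 1 bp with the best signal. Against the GC-matched background, which held far fewer windows, 266 6-mers were more and 392 less frequent. Each list alone has unknown depth, so how depth limits weak peaks could not be assessed. No paired analysis was possible because the series has 1 group.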

Other observations

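Further gene families were tested in the same way as the fixed lists. They were chosen after the fixed lists had been seen, the synthetase genes after ears-2 had appeared among the strongest peaks, and the cytochrome P450 family was narrowed from a broader draft before it was run. By two-sided Fisher's exact tests with adjustment over the 4 added families, nuclear pore and importin genes had 13 of 32 promoters occupied (40.6%, odds ratio 7.40, adjusted p = 1.7e-06), led by npp-8 (signal 273) and ima-1 (194). Mitochondrial ribosomal protein genes had 21 of 70 (30%, odds ratio 4.65, exact-test adjusted p = 7.8e-07), led by mrpl-23 (181) and mrps-7 (160). Aminoacyl-tRNA synthetase genes had 7 of 32 (21.9%, odds ratio 3.02, Fisher's exact test, adjusted p = 0.016), with ears-2 (371) and tars-1 (125). The 7 include ears-2, which had prompted the choice, so this result is not independent of that peak. Cytochrome P450 genes, a family of metabolic enzymes, had 0 of 74 (0%, exact-test adjusted p = 0.0035).

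Annotated tRNA genes and tRNA pseudogenes differed sharply, in a test chosen when the share of tRNA genes was known and that of pseudogenes was not. These groups were not matched on copy number. Among the 140 tRNA genes without an identical copy elsewhere, 21.4% were occupied. Of 209 annotated tRNA pseudogenes, 3 (1.44%, 95% Wilson interval 0.489 to 4.13%) had an IDR summit within 500 bp, close to the 1.76% of circular shifts, against 31.7% (28.1 to 35.5%) of the 612 tRNA genes (two-sided Fisher's exact test, p = 9.4e-25). The genes for the RNA of RNase P, rpr-1 (signal 263, rank 71), and of RNase MRP, mrpr-1 (230, rank 113), also had IDR peaks, and were chosen after their values were seen. The microRNA genes mir-51 and mir-52, looked up at the same time, had none.

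The replicates ranked kinds of peaks somewhat differently. Among IDR peaks matched in both lists, 41.8% of the 1075 promoter peaks without a nearby tRNA, snoRNA or small nuclear RNA gene ranked better in replicate 3 than in replicate 2, against 56.9% of the 357 such peaks outside promoters. Of peaks on X, 52.3% ranked better in replicate 3, against 44.6% on autosomes. These values describe 2 libraries and were not tested.

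3 patterns were weighed against technical explanations; the tests of highly transcribed genes and of low-ranked peaks on X, and the separate reading of the multi-copy share, were chosen after the results were seen. For the signal at tRNA genes, 21.4% of 140 single-copy genes had a summit (95% Wilson interval 15.4 to 28.9%), where the shifts gave at most 8.57%. Single-copy here means only that no identical full-length sequence occurs elsewhere. Reads could still be shared with nearly identical copies, and a summit within 500 bp can belong to a neighbouring gene. Shared reads as the whole cause could therefore not be excluded. The higher share that shared reads predicted beforehand was also found, with 34.7% of the 472 multi-copy genes (two-sided Fisher's exact test, p = 0.0027), so they may still raise the share among those genes. Neighbouring promoters are argued against by the 31.7% occupied among the 382 tRNA genes over 1000 bp from every coding 5′ end, where the mean of the shifts was 2.16%. A link to RNA polymerase III promoter sequence is a candidate explanation, with a difference of 32.2 percentage points between genes with and without a B box (Fisher's exact test, p = 0.035), although only 10 genes lacked one and none of them was occupied. Of the 602 genes with a B box, 194 were occupied, so its presence does not tell which tRNA genes are occupied. Non-specific recovery at highly transcribed genes stays open, because ribosomal protein genes, with 74.4% occupied, would show it as well as a specific protein would, and no list from an untagged strain was analysed here.

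For the higher density of peaks on X, tRNA genes did not account for all of the excess, since X still held 19.6% of the peaks without them (95% Wilson interval 17.8 to 21.6%) for 17.7% of the length, although the lower bound is only just above that. Greater depth or mappability of X as the whole cause is argued against by the 18.5% (17.9 to 19.2%) on X below rank 15000 of the pooled list, against 22.2% of the IDR list. For the excess left without tRNA genes it cannot be told apart from other causes, since the difference there is 1.11 points and the interval of 17.8 to 21.6% contains 18.5%. What remains of the excess is small beside the range among autosomes, from 10.2 to 21.6 such peaks per Mb, and no biological explanation was tested.

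For the peak at the F13C5.2 promoter, extra copies of the locus in the integrated transgene may raise local read counts. The 26 pooled-list peaks within 20 kb had a median rank of 7558.5, against 14833.5 in the median window of X, and 6.15% of 943 windows were better (95% Wilson interval 4.79 to 7.87%), which spans the bound of 5% set beforehand. By that bound alone the explanation would have been rejected, and the interval was taken into account only after the value was seen. The windows were random draws and can overlap, so the interval covers only the error of drawing, not the uncertainty about the locus. Extra copies and binding at its own promoter cannot be told apart from these lists, and ranks of 5 and 123 in the replicates leave the strength uncertain as well.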
